A study of Homo sapiens with 10 samples.

How the data were processed

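RNA was measured on 10 one-colour arrays, 3 of HMC-1 cells, 4 of the high density (HD) and 3 of the low density (LD) fraction of extracellular RNA. Per the labels total RNA was amplified as amino allyl RNA and labelled with Cy5. For each array the authors deposited the raw intensity of each spot, a background-subtracted intensity and a normalized intensity. Checked on the values, the subtracted background is 1 constant per array, equal to the mean of the 2680 blank spots after trimming 5% at each end, and a spot is left empty unless its raw intensity lies at least 2 SD above that mean. The deposited normalized intensity is the background-subtracted intensity times 1 factor per array, which puts the median of the detected gene probes at 25. The authors also deposited a series matrix of log2 values; its ranks follow the raw intensity and its medians lie between 5.84 and 5.852 on all arrays, as after quantile normalization without background subtraction. The scanner software and the RNA input per array are not stated. Gene names came from a reference table of GRCh38.p14 used for names alone: 21062 of 24460 gene probes were named, covering 18709 genes, and 3398 were not.

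The depth of an array is its number of detected probes, from 878 (HD 1) to 11653 (Cell 2), and the number of arrays limits the precision. Normalized intensities were taken to log2, undetected probes were set to the lowest detected value of their own array, and spots with a quality flag were left missing. These floors lie between 2.14 and 2.79 in Cell, 3.46 and 4.10 in LD and 3.94 and 4.20 in HD, so a probe absent from both groups can appear higher in HD or LD; results are therefore also counted where the brighter group was detected on every array. A fold against a group with no detection is given as a lower limit, or not at all where the floors reach the level of the other group, and a fold against a group detected on some arrays is understated. Probes entered the tests if detected on every array of at least 1 group (9333 probes, 7835 genes). Where several probes named a gene, the brightest stood for it in the lists; 608 genes had several tested probes, of which 26, 10 and 0 had probes called in opposite directions in HD against Cell, LD against Cell and HD against LD.

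The 3 comparisons were made in 1 limma model over all 10 arrays with group as the only term, empirical Bayes variances, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, for lists with at least 3 tested members. There were 26 lists: cytosolic and mitochondrial ribosomal proteins, translation factors, nuclear and mitochondrially encoded oxidative phosphorylation, mast cell markers, vesicle biogenesis and tetraspanins, cell cycle, glycolysis, proteasome, spliceosome, endoplasmic reticulum secretory machinery, immediate early genes, cytokines, heat shock, cholesterol and fatty acid synthesis, cytoskeleton, nuclear noncoding RNAs, histones, zinc finger genes, olfactory receptors, and markers of 5 groups of other cell types. Numbers of detected probes and correlations with the mean Cell array were compared with exact two-sided permutation tests. The comparisons, lists, tests, the rule for named genes and most alternatives were fixed before the data were examined.

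The genes named were chosen by rule in each comparison: the 8 highest and 8 lowest called probes detected on every array of both groups and without overlap between them; up to 4 probes per direction detected on every array of one group and none of the other; of each list described, up to 2 called members per direction, or otherwise its 2 brightest; and KIT, TPSAB1, CPA3, HDC, CD63, CD81, CD9, GAPDH and ACTB. Part of the genes given by this rule are described. TPSAB1 was not tested. Members of short counts outside this rule were named after their values were seen, namely ZNF331 and ZNF800 in HD against Cell, RPL5, RPL13 and RPL34, the olfactory receptor genes, AURKB, H1-2, H3C7, KRT19, SNHG12 and GNG3. Pseudogene probes such as RPLP1P4 cannot be told from their parent genes and are not described.

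The series states that arrays 1 to 3 of each kind share a culture. After removal of group means, arrays with the same number correlated over the tested probes at 0.209, 0.147 and −0.121 for Cell and HD, 0.0849, 0.141 and 0.0646 for Cell and LD, and −0.108, 0.146 and 0.218 for HD and LD, and some pairs with different numbers correlated as much. HD 4 has no partner, so the culture number entered as a block only in an alternative. File names give 2 scan days: the 3 Cell arrays, HD 4, LD 1 and LD 2 were scanned on day 1 and HD 1 to HD 3 and LD 3 on day 2. Scan day was used as a block and comparisons were repeated within a day.

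The alternatives fixed in advance were normexp background correction (offset 50) with quantile normalization, scaling to the median of probes detected on all 10 arrays or to the 75th percentile of all gene probes, quantile normalization of the deposited values, the series matrix values, no filter, only probes detected on all 10 arrays, undetected values left missing, only the arrays of the 2 groups compared, a trended and robust variance, array weights, a culture block, a random culture block, a scan day block, single scan days, a 2-fold minimum, a detection limit at the mean plus 2 SD of all blank spots without trimming, Spearman correlation, an estimated list correlation and leaving out each array. Added after the data were seen were a common floor for all arrays, leaving out HD 1 with HD 3 or HD 4 with LD 3, detection at 5 SD above the blanks, and the brightest unflagged probe per gene in the lists. The probe standing for a gene was at first chosen in a different order in the alternatives and splits than in the main test; the main order is now used everywhere, and the other order is that last alternative.

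The tests were tried on simulated data with 200 probes changed per comparison. In HD against Cell 64, 96, 96 and 100% of probes raised 2, 4, 8 and 16-fold were called, and 20, 60, 48 and 56% of those lowered; in LD against Cell 48, 92, 96 and 100% and 4, 44, 44 and 36%; in HD against LD 20, 76, 100 and 100% and 12, 36, 52 and 44%. Among unchanged probes 547 of 8867 were called higher in HD against Cell, 30 of them detected on every HD array, and 19 lower; the numbers were 22, 5 and 7 of 8869 in LD against Cell, and 1 higher and 3 lower of 8883 in HD against LD. In the lists 1 of 1 shifted and 0 of 20 unchanged were called. These simulated lists had no floors and no correlation between genes, so they do not show how often real lists are called falsely. Work was done in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.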

Results

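RNA of HMC-1 cells, a human mast cell line, was measured on 1-colour arrays together with RNA that the cells had released. Mast cells are immune cells of tissues that store histamine and proteases in granules. The released RNA came from the culture medium by ultracentrifugation and was parted on a density gradient into a high density (HD) and a low density (LD) fraction. There were 3 arrays of cells (Cell), 3 of LD and 4 of HD, and arrays with the same number from 1 to 3 come from one culture. The series text names 4 HD replicates but counts 9 samples in all, against 10 arrays deposited. HD 4 has no Cell or LD partner, and HD means and SDs with n = 4 include it. The question named for the study is whether a single cell type releases distinct populations of extracellular RNA.

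The arrays carried 24460 gene probes. The Cell arrays detected 10993, 11653 and 11637 of them, LD 1 to LD 3 detected 5830, 4509 and 2789, and HD 1 to HD 4 detected 878, 3276, 1825 and 5347. Blank spots passed the same detection limit at a rate of 6.16 to 8.25%, which alone would give 1506 to 2017 probes, so that HD 1 lay below and HD 3 within that range. The limit was set after the top 5% of these blanks were trimmed, which raises their rate. Of 96 negative control spots per array 1 to 7 passed the limit, 2 on HD 1 and 4 on HD 3. The mean number of detected probes in HD minus Cell was −8596 (exact permutation p = 0.0571, two-sided; 0.15 adjusted over the 3 pairs) and in LD minus Cell −7052 (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow; adjusted 0.15). With the limit set from all blank spots, without trimming, these differences were −4612 (exact permutation p = 0.114) and −2499 (exact permutation p = 0.4), and Cell 3 detected 363 probes. The difference between HD and LD did not pass (−1544.5, exact permutation p = 0.343, adjusted 0.343), and on scan day 1, with HD 4 as the only HD array, it was 177.5. The 10 brightest probes held 92.6% of the background-subtracted signal on HD 1, which has 1 saturated spot, 39.2 to 52.8% on HD 2 to HD 4, 14.8 to 16.5% in LD and 8.68 to 9.74% in Cell.

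LD resembled the cells more closely than HD did. Across the 9333 tested probes, which are not independent replicates, the correlation with the mean Cell array was 0.818, 0.749 and 0.658 for LD 1 to LD 3 and 0.141, 0.119, 0.106 and 0.489 for HD 1 to HD 4. The group means were 0.741 and 0.214 (difference HD minus LD −0.53, exact permutation p = 0.0571, two-sided). On each of the 2 scan days every LD array lay above every HD array: day 1 held LD 1, LD 2 and HD 4, and day 2 held LD 3 and HD 1 to HD 3. Signal was not matched within a day. Positive Control 1 spots, whose target is not stated, lay 5531, 3431 and 635 above background on LD 1, LD 2 and HD 4. They lay 578 above it on LD 3, 3.67 to 15.5 on HD 1 to HD 3 and 10379 to 19380.5 on Cell arrays. The order within a day therefore cannot be told apart from a difference in signal. Of the 500 brightest Cell probes, 470 were detected on every LD array and 56 on every HD array. HD 1 to HD 4 detected 96, 184, 99 and 493 of them.

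**Figure D1:**
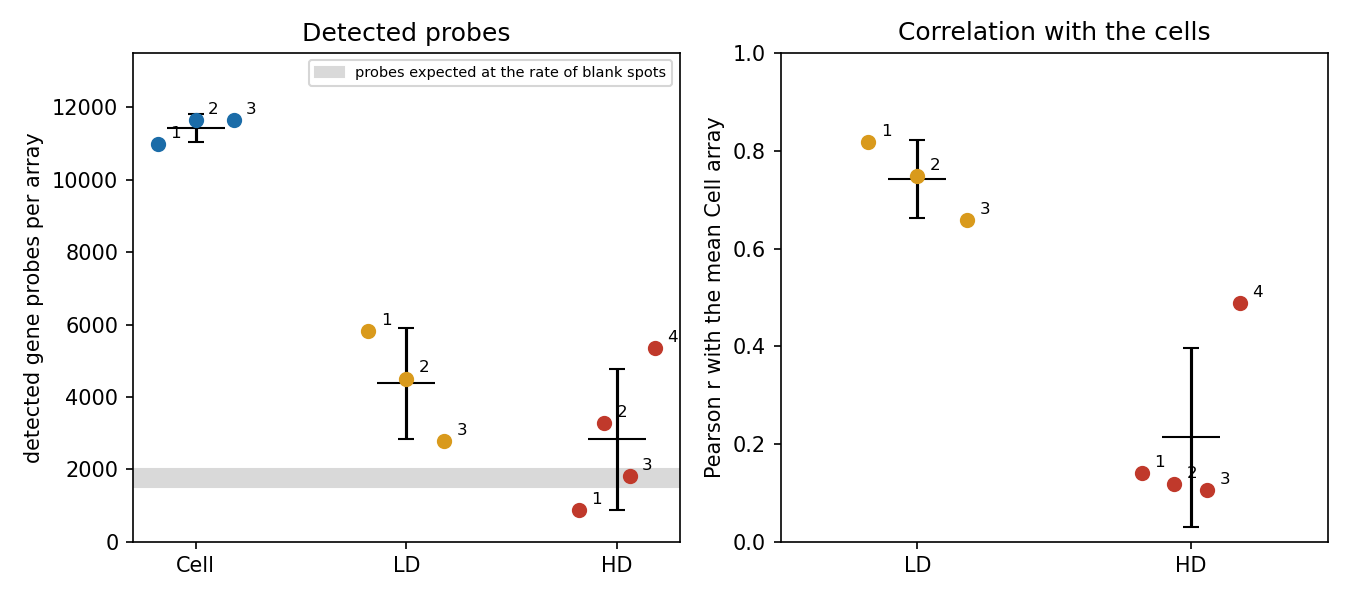
The left panel plots detected gene probes per array and the right panel the Pearson correlation of each LD and HD array with the mean Cell array; points are arrays with their number, lines are means, bars are SD and the grey band is the number of probes expected at the rate of blank spots. HD 4 stands above the other HD arrays in both panels, with 5347 probes and a correlation of 0.489.

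HD against Cell asks which messenger RNAs of the cells the high density fraction carried. The messenger RNAs of the protein synthesis machinery were low in HD: RPL3, of the large ribosomal subunit, had a log2 level of 6.69 ± 2.43 (SD, n = 4) in HD and 14.07 ± 0.27 (SD, n = 3) in Cell. KIT, the stem cell factor receptor that mast cells depend on, was detected on 1 of 4 HD arrays, with a log2 fold change of −6.14 ± 0.66 (SE, adjusted p = 9.14e-06). HDC, the enzyme that makes histamine, fell by 5.68 ± 0.68 on the log2 scale and was also detected on 1 of 4 HD arrays. A small set of transcripts was brighter in HD, among them FITM1, a protein of lipid droplet formation (log2 fold change 3.67 ± 0.46 SE, adjusted p = 2.76e-05), and FGFR1, a fibroblast growth factor receptor (3.26 ± 0.56, adjusted p = 0.000304). In limma, 6023 of 9333 probes passed at adjusted p 0.05; 4920 were lower in HD, of which 2660 were detected on no HD array, and 1103 were higher. Because undetected probes take the floor of their array, and HD floors lie above Cell floors, only 127 of the 1103 were detected on every HD array, and those alone are described as higher below. With one common floor for all arrays the 1103 became 98 and the 127 became 91, and with scan day as a block they became 628 and 158. The 127 also became 283 without HD 1, 204 without HD 3, 805 without both, 467 within scan day 1 (HD 4 alone for HD), 344 under normexp, 349 under quantile normalization, 337 with the series matrix values and 194 at the 75th percentile. All higher probes numbered 1721 without Cell 3.

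Most translation and energy genes fell in HD. Of 50 tested cytosolic ribosomal protein genes 47 fell, with a median log2 fold change of −6.47 (camera adjusted p = 8.01e-06; adjusted p = 0.438 with an estimated correlation). RPLP1 changed by −6.91 ± 0.94 and RPS18, detected on 1 HD array, by −8.23 ± 1.08. The per-array median of this list was 11.84, 11.95 and 11.92 in Cell, 4.09, 4.62 and 4.20 in HD 1 to HD 3, and 7.79 in HD 4. Of 32 translation factor genes 28 fell, EEF1G at −6.76, and EIF4G1 was higher with detection on every HD array (1.24 ± 0.50, adjusted p = 0.0454). That call was lost without HD 2, HD 4, LD 2 or any Cell array (adjusted p from 0.0604 to 0.129). The translation factor median was −3.45 (adjusted p = 0.000516; adjusted p = 0.401 with an estimated correlation). All 65 nuclear genes of oxidative phosphorylation fell, with ATP5F1B of the ATP synthase at −5.82 ± 0.66. The oxidative phosphorylation median was −4.03 (adjusted p = 4.87e-09; adjusted p = 0.401 with an estimated correlation). All 7 genes encoded by mitochondrial DNA fell, with MT-ND4L at −6.61 ± 0.69 and MT-CYB at −6.58 ± 0.93. The mitochondrially encoded median lay between that of oxidative phosphorylation and the −3.89 of the cytoskeleton list (adjusted p = 0.0224; adjusted p = 0.401 with an estimated correlation). Of 73 mitochondrial ribosomal protein genes 66 fell, MRPS21 at −4.35. The mitochondrial ribosomal median was −2.27 (adjusted p = 1.33e-06; adjusted p = 0.363 with an estimated correlation). Of 20 glycolysis genes 17 fell, with ENO1 at −7.79 and GAPDH at −7.38 ± 0.93. The glycolysis median was −3.19 (adjusted p = 0.00426; adjusted p = 0.327 with an estimated correlation).

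Genes of cell structure and protein quality were also mostly lower in HD. On HD 1 and HD 3 the median of every list lay at the floor, so the falls of list medians are understated. Each fall is bounded there by the level of the list in Cell. Cell medians were 11.84 to 11.95 for the ribosomal, 6.78 to 7.11 for the secretory and 5.99 to 6.64 for the cell cycle list. The order of the lists by fall therefore partly follows their Cell level, and the list tests share this limit. In the cytoskeleton list 34 of 38 genes fell; TMSB4X, which binds actin monomers, stood at −8.11 and ACTG1 at −7.14. The cytoskeleton median was −3.89 (adjusted p = 4.37e-05; adjusted p = 0.401 with an estimated correlation). In the proteasome list 41 of 42 fell, PSMB1 at −5.70. The proteasome median was −3.36 (adjusted p = 8.46e-07; adjusted p = 0.327 with an estimated correlation). Of 55 spliceosome and hnRNP genes 48 fell, HNRNPA2B1 at −5.84. The spliceosome median was −3.23 (adjusted p = 4.13e-06; adjusted p = 0.327 with an estimated correlation). Of 48 genes of the secretory machinery of the endoplasmic reticulum 43 fell, SRP14 of the signal recognition particle at −6.02. The secretory median was −2.79 (adjusted p = 2.04e-06; adjusted p = 0.0682 with an estimated correlation). Heat shock and chaperone genes fell in 29 of 34 cases, CCT8 at −5.03. The chaperone median was −2.84 (adjusted p = 0.00208; adjusted p = 0.327 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell in 27 of 28 cases, FDPS at −5.84. The cholesterol median was −2.30 (adjusted p = 6.44e-05; adjusted p = 0.101 with an estimated correlation). Cell cycle genes fell in 45 of 55 cases, PCNA, the sliding clamp of DNA polymerase, at −4.76. The cell cycle median was −1.98 (adjusted p = 0.00168; adjusted p = 0.438 with an estimated correlation). Replication-dependent histone genes fell in 15 of 18 cases. The histone median was −2.32 (adjusted p = 0.0101; adjusted p = 0.327 with an estimated correlation).

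Of 27 tested mast cell markers 19 fell in HD. The mast cell median was −2.66 (adjusted p = 0.0489; adjusted p = 0.438 with an estimated correlation). SRGN, the core protein of granule proteoglycans, fell by 6.14 ± 0.60 and was detected on 1 HD array. CPA3, the mast cell carboxypeptidase, was detected on no HD array, and because the HD floors average 4.06 and its Cell mean was 3.67, no fold is given. Tetraspanins, membrane proteins used as markers of extracellular vesicles, were lower: CD63 at −6.52 ± 0.82 and CD9 at −4.72 ± 0.30, while CD81 was at least 3.19-fold lower, a direction that turned (0.42) when arrays were scaled to the 75th percentile. Of 52 vesicle biogenesis and tetraspanin genes 37 fell and the list test missed its threshold (median −1.80, adjusted p = 0.0504). Of 31 immediate early genes 20 fell (median −1.41, adjusted p = 0.221), DUSP6 at −5.41, and of 21 cytokine genes 7 fell (median −0.08, adjusted p = 0.154), MIF at −6.81. ACTB was detected on 2 HD arrays and changed by −5.78 ± 0.85, a call lost under quantile normalization, normexp and the series matrix values.

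Zinc finger genes moved both ways in HD: 53 of 175 fell and 4 were higher with detection on every HD array, ZNF441 (3.04 ± 0.42), ZNF620 (2.77 ± 0.46), ZNF331 (1.87) and ZNF800 (1.04). The list test placed them above other genes (median −0.04, adjusted p = 4.37e-05; adjusted p = 0.401 with an estimated correlation). The median of the list lay at the floor on all 4 HD arrays and between 4.03 and 4.42 in Cell, so it had little room to fall and this position is set by the floors. Olfactory receptor genes, which are silent in most tissues, were also placed above other genes (median 0.58, adjusted p = 2.38e-08; adjusted p = 0.327 with an estimated correlation). Their median lay at the floor on HD 1 and HD 3 and was 3.49 to 4.25 in Cell, and with one common floor it was 0.12, so this position too rests largely on the floors. Of 36 genes 2 fell, and OR1J1, OR2W3, OR4D6 and OR5AR1, named after their values were seen, were higher with detection on every HD array. KRT18, a keratin of simple epithelia, was detected on no Cell array and was at least 19.4-fold higher in HD. Adjusted over the list alone, the numbers of lower genes equalled those above except for 29 translation factor, 18 glycolysis and 50 zinc finger genes. Among markers of other cell types, 3 of 7 erythroid and platelet genes, 3 of 5 lymphocyte genes (4 adjusted over the list alone), 2 of 4 monocyte and granulocyte genes, 1 of 7 fibroblast, endothelial and epithelial genes and none of 2 liver genes fell, and none of these lists passed (adjusted p from 0.169 to 0.838).

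The median of all tested probes in HD against Cell depended on the scaling. It was −0.81 in the main values, −0.60 under quantile normalization, −0.35 with the median of probes on all 10 arrays, −0.0944 under normexp, −0.0986 with the series matrix values and 1.29 at the 75th percentile. The last gave 2230 higher and 503 lower probes, and 194 of the 2230 were detected on every HD array. Such detection cannot settle the direction, because 408 probes were detected on every HD array and 9281 on every Cell array. At that scaling the medians of the vesicle (0.30), cell cycle (0.12), immediate early (0.68), cytokine (2.01) and zinc finger (2.06) lists were positive. HD arrays detected 3.59 to 21.9% and LD arrays 11.4 to 23.8% of gene probes, too few for the 75th percentile to lie among detected probes. That percentile was 0.126 to 5.64 above background in HD, 0.706 to 1.95 in LD and 8.64 to 15.8 in Cell. Shifts at this scaling therefore rest on a value below the detection limit of each HD and LD array. Probes called numbered 5764 with the culture number as a block, 5370 with scan day as a block and 4351 within scan day 1. On that day HD 4 is the only HD array and is assumed to vary like the other groups; there the ribosomal median was −3.92, that of oxidative phosphorylation −3.39, that of mitochondrially encoded genes −3.20 and that of the cytoskeleton −3.48.

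**Figure D2:**
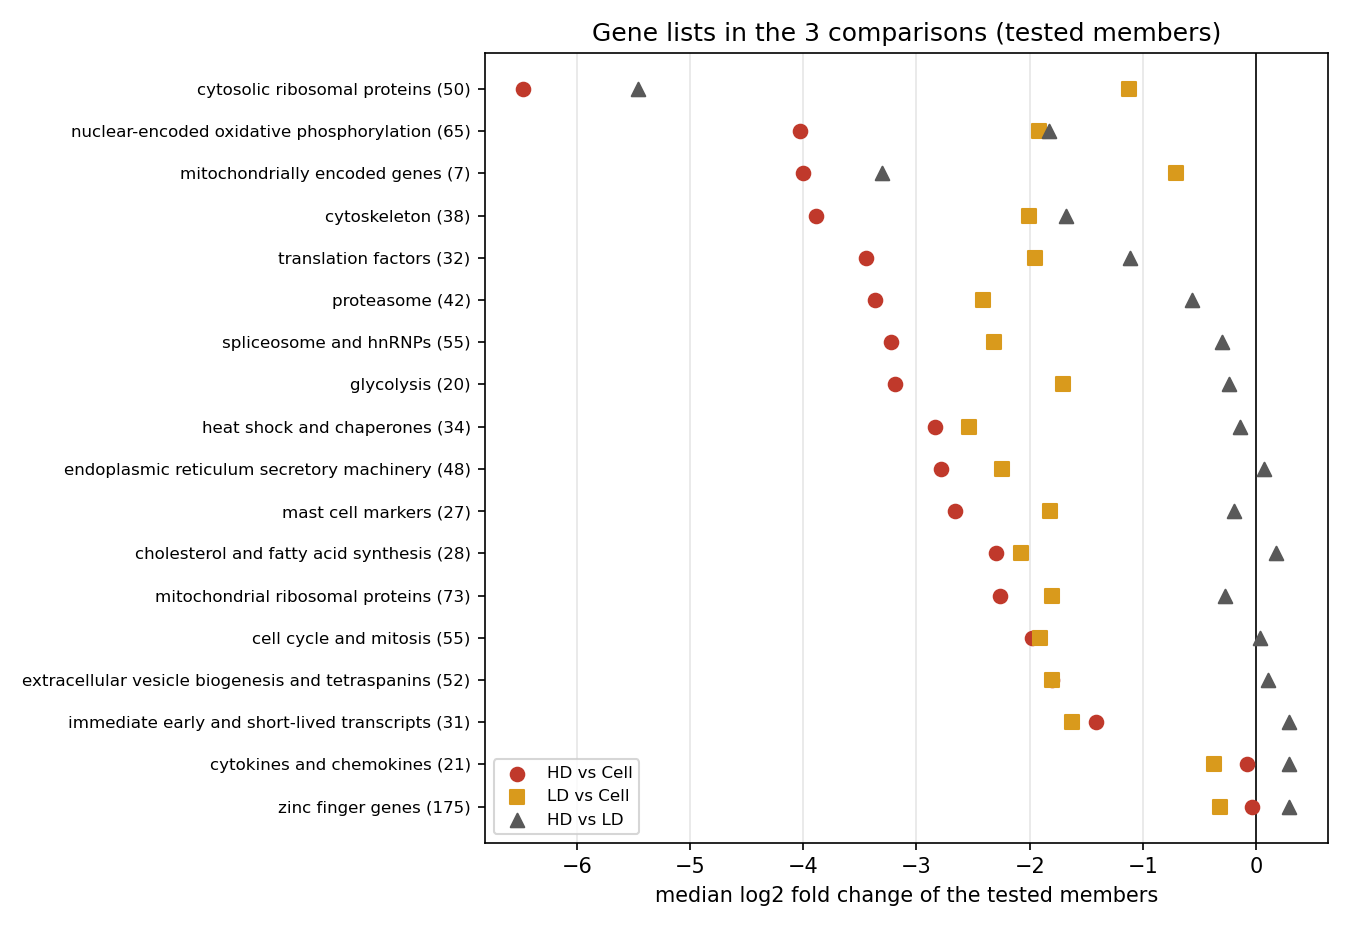
Each point is the median log2 fold change of the tested members of a gene list (number of members in brackets) in HD against Cell (circles), LD against Cell (squares) and HD against LD (triangles). The ribosomal list lies at −6.47, −1.12 and −5.46. Scaling to the 75th percentile moves the LD against Cell value of this list to 0.05. It also turns the vesicle, cell cycle, immediate early, cytokine and zinc finger values of HD against Cell. On HD and LD arrays that percentile lies among undetected probes.

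LD against Cell asks the same of the low density fraction. Of the messenger RNAs at high level in the cells, some were also bright in LD and others far lower. GAPDH had a log2 level of 11.83 ± 1.00 (SD, n = 3) in LD and 12.74 ± 0.21 (SD, n = 3) in Cell (log2 fold change −0.90 ± 0.99 SE, adjusted p = 0.462), and MT-ND4L, a subunit of respiratory complex I, 12.29 ± 0.50 and 11.80 ± 0.48 (0.49 ± 0.74, adjusted p = 0.597). B2M, the light chain of class I histocompatibility proteins, fell from 12.01 to 7.66 (−4.35 ± 0.80, adjusted p = 0.000721), and RHEX from 11.32 to 6.56 (−4.76 ± 0.82). KIT was detected on 1 of 3 LD arrays (−5.92 ± 0.71, adjusted p = 3.36e-05), HDC on 2 (−4.63 ± 0.73), and SLC18A2, the transporter that loads histamine into granules, on none, at least 23.0-fold lower. TMEM59 changed by −4.36 ± 0.34 (adjusted p = 2.9e-06) and SLC2A3, a glucose transporter, by −6.01 ± 0.45. In limma 5188 of 9333 probes passed; 4783 were lower, 1510 of them detected on no LD array, and 405 were higher, of which 66 were detected on every LD array. With one common floor both numbers became 20, and at the 75th percentile 0. The 66 became 128 under normexp, 214 under quantile normalization, 109 with the series matrix values, 102 with scan day as a block, 137 within scan day 1, 204 without HD 4 and LD 3, 183 without LD 3, 107 without LD 1 and 40 without Cell 1, and the 405 became 875 without Cell 3 and 247 without LD 2. Among these 66 were MYOM3, a protein of the muscle M band (2.61 ± 0.52, adjusted p = 0.00126), GM2A, a lysosomal activator of ganglioside breakdown (2.59 ± 0.50), and CENPI, of the kinetochore (2.41 ± 0.41).

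Few ribosomal and mitochondrially encoded genes were called in LD. Of 50 ribosomal protein genes 5 fell (RPL22, RPL15, RPL5, RPL13 and RPL34), and 45 were detected on every LD array. The list was not called (camera adjusted p = 0.0812, direction up). Its median of −1.12 lay below the −0.90 of all tested probes, so by fold change the list did not rank above other genes. The number of genes that fell was 23 without HD 4 and 24 with culture number as a block. RPL15 lost its call without Cell 1, Cell 3 or LD 3 (limma adjusted p from 0.0504 to 0.0841), and 2 genes fell when adjusted over the list alone. The model shares its estimate of the spread over all groups. The ribosomal median was 7.79 on HD 4 and 4.09 to 4.62 on HD 1 to HD 3, a spread that enters these tests. Few calls therefore do not show an unchanged level in LD. Of 7 mitochondrially encoded genes MT-ND6 fell (−2.59 ± 0.45; list median −0.70, adjusted p = 0.259). MT-CYB changed by −1.27 ± 1.00 (adjusted p = 0.302), with adjusted p = 0.00975 with culture number as a block and 0.0286 without HD 4, and 3 genes of the list fell under either. ACTB changed by −1.04 ± 0.91 (adjusted p = 0.354; 0.0461 with culture number as a block).

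Other lists were lower in LD. The medians of the secretory, cholesterol, cell cycle and chaperone lists lay at the floor on LD 2 and LD 3. Those of the proteasome, spliceosome and mitochondrial ribosomal lists did so on LD 3. There the falls are bounded by the Cell level of each list, which limits comparison between lists. Of 48 genes of the endoplasmic reticulum secretory machinery 44 fell (median −2.25, adjusted p = 6.94e-07), and this call held with an estimated correlation (adjusted p = 0.0465); PDIA6, which forms disulphide bonds in new secretory proteins, was detected on 1 LD array (−4.23 ± 0.31). Of 28 cholesterol and fatty acid synthesis genes 26 fell, with INSIG1, a sterol sensor partner, at −4.50 ± 0.22 and MSMO1 at −3.75. The cholesterol median was −2.08 (adjusted p = 1.44e-05; adjusted p = 0.0564 with an estimated correlation). Of 42 proteasome genes 40 fell, PSMC2 at −3.86. The proteasome median was −2.41 (adjusted p = 1.29e-05; adjusted p = 0.399 with an estimated correlation). Of 55 spliceosome and hnRNP genes 47 fell, SRSF5 at −4.69. The spliceosome median was −2.31 (adjusted p = 3.12e-05; adjusted p = 0.399 with an estimated correlation). Of 73 mitochondrial ribosomal protein genes 66 fell, MRPS30 at −3.15. The mitochondrial ribosomal median was −1.80 (adjusted p = 3.89e-05; adjusted p = 0.499 with an estimated correlation). Of 65 nuclear oxidative phosphorylation genes 56 fell, ATP5F1C at −3.29. The oxidative phosphorylation median was −1.92 (adjusted p = 0.00175; adjusted p = 0.61 with an estimated correlation). Of 55 cell cycle genes 46 fell, CDK1, the kinase that drives mitosis, at −4.01. The cell cycle median was −1.91 (adjusted p = 0.000824; adjusted p = 0.555 with an estimated correlation). Of 34 heat shock and chaperone genes 28 fell, CCT3 at −3.72. The chaperone median was −2.54 (adjusted p = 0.00218; adjusted p = 0.399 with an estimated correlation).

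Of 52 vesicle biogenesis and tetraspanin genes 36 fell in LD. The vesicle median was −1.80 (adjusted p = 0.03; adjusted p = 0.399 with an estimated correlation). CD9 stood at −4.66 ± 0.32, detected on 1 LD array, CD81 at −1.89 ± 0.27, and CD63 at −4.09 ± 0.88 with detection on every LD array. The mast cell list missed its threshold (21 of 27 fell, median −1.82, camera adjusted p = 0.0553). CPA3 was detected on no LD array. The floors there were 3.46, 3.76 and 4.10, against Cell levels of 3.16, 4.39 and 3.46, so no fold is given. Histone genes fell in 16 of 18 cases (median −1.84, adjusted p = 0.0189; adjusted p = 0.399 with an estimated correlation), translation factor genes in 26 of 32 (median −1.95, adjusted p = 0.0438; adjusted p = 0.555 with an estimated correlation) and cytoskeleton genes in 29 of 38 (median −2.00, adjusted p = 0.0438; adjusted p = 0.61 with an estimated correlation), with EIF4A2 at −4.05 and ACTR3 at −4.32. The glycolysis (16 of 20 fell, adjusted p = 0.0812), immediate early (20 of 31, adjusted p = 0.0638) and cytokine lists (7 of 21, adjusted p = 0.174) did not pass; MCL1, a short-lived survival factor, fell by 3.67 ± 0.24. Zinc finger genes (54 of 175 fell, median −0.32, adjusted p = 0.0014; adjusted p = 0.555 with an estimated correlation) and olfactory receptor genes (OR2T11 of 36 fell, median 0.24, adjusted p = 6.94e-07; adjusted p = 0.399 with an estimated correlation) were placed above other genes. The zinc finger median lay at the floor on every LD array and the olfactory median was −0.01 with one common floor, so the floors set these positions. ZNF620 was higher with detection on every LD array (1.54, adjusted p = 0.019), a call lost without Cell 1, LD 1 or LD 2 (adjusted p from 0.0612 to 0.0784). Adjusted over the list alone, the numbers of lower genes differed for oxidative phosphorylation (61), mitochondrial ribosomal (67), spliceosome (49), secretory (45), heat shock (29), zinc finger (53) and olfactory (0) genes. Among markers of other cell types 3 of 7 erythroid, 2 of 5 lymphocyte, 1 of 4 monocyte (0 adjusted over the list alone) and 4 of 7 fibroblast, endothelial and epithelial genes fell, none of 2 liver genes did, KRT18 was at least 6.03-fold higher (a call lost with one common floor), and no list passed (adjusted p from 0.234 to 0.524).

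By the number of calls, LD against Cell rests on the scaling more than the other comparisons. Scaling to the 75th percentile, which lies below the detection limit on every LD array, left 2 called probes, KIT and SLC2A3 of the genes named here. It moved the median of all tested probes from −0.90 to 0.27, a smaller move than the −0.81 to 1.29 in HD against Cell. The ribosomal median turned to 0.05 there. The mitochondrially encoded median turned positive there (0.46) and under normexp (0.46), the series matrix values (0.45) and quantile normalization (1.02). Of the genes named, B2M, RHEX, HDC, CD63, MT-ND6, RPL22, RPL15, ATP5F1C and EIF4A2 also lost their calls under quantile normalization, and B2M, CD81 and CENPI with the series matrix values. Called probes numbered 5299 with culture number as a block, 5239 with scan day as a block and 4528 within scan day 1, where the ribosomal median was −0.47 and that of the secretory machinery −1.97.

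**Figure D3:**
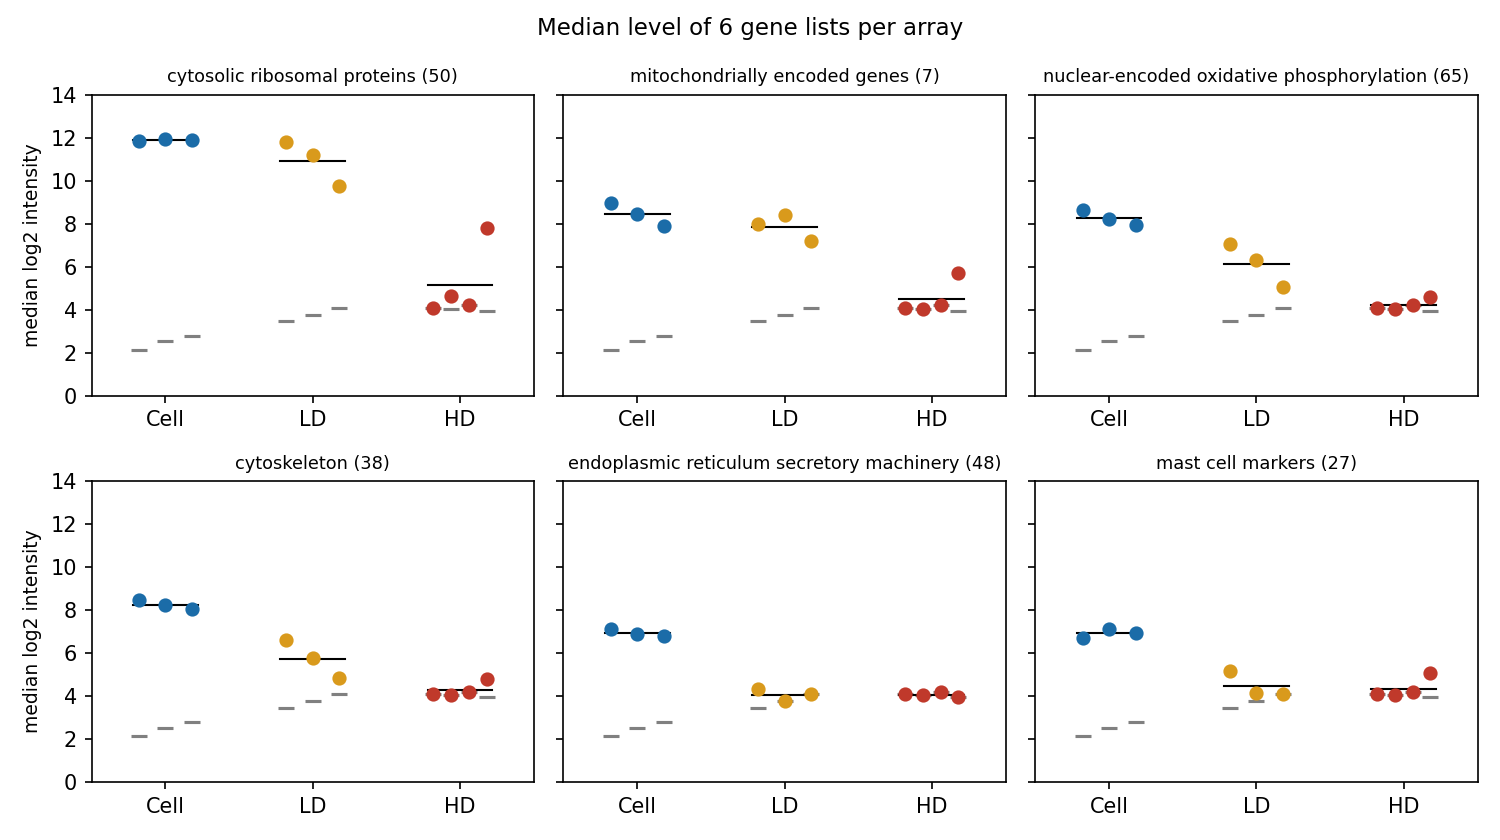
Each panel plots the median log2 intensity of the tested members of a gene list on each array; black lines are group means and grey lines the floor of each array. Ribosomal medians are 11.82, 11.23 and 9.74 in LD and 7.79 in HD 4, against 4.09 to 4.62 in HD 1 to HD 3, which lie close to their floors.

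HD against LD asks whether the fractions differ from each other. Among the lists, cytosolic ribosomal protein and mitochondrially encoded genes were most often lower in HD, though no list passed with an estimated correlation. RPLP1, of the ribosomal stalk, had a log2 level of 7.31 ± 2.07 (SD, n = 4) in HD and 13.17 ± 1.28 (SD, n = 3) in LD (log2 fold change −5.86 ± 0.94 SE, adjusted p = 0.00178). MT-ND4L was detected on 2 HD arrays and changed by −7.10 ± 0.69 (adjusted p = 0.000192), and GAPDH by −6.48 ± 0.93 (adjusted p = 0.000967). Few genes were brighter in HD, among them SLC2A14, a glucose transporter (2.10 ± 0.37, adjusted p = 0.00318), ZNF331, a zinc finger protein (1.75 ± 0.33, adjusted p = 0.00533), and FBXW7, which marks proteins for degradation (1.53 ± 0.26, adjusted p = 0.00258). In limma 761 of 9333 probes passed, 733 lower in HD, of which 731 were detected on every LD array, and 28 higher, all detected on every HD array. The 28 became 12 with one common floor, 64 with scan day as a block (63 detected on every HD array), 129 without HD 1 and HD 3, 45 without HD 1, 18 without HD 2, 49 without HD 3 and 15 without LD 1. KIT (−0.22 ± 0.66, adjusted p = 0.82), HDC (−1.05, adjusted p = 0.503) and CD9 (−0.06, adjusted p = 0.888), each detected on 1 of 4 HD arrays and on 1 or 2 of 3 LD arrays, did not pass. CD81 was detected on no HD array and 1 LD array, and no fold is given.

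Of 50 cytosolic ribosomal protein genes 42 were lower in HD than in LD, RPS29 at −5.59 ± 0.74 and RPL10 at −5.30 ± 0.66; 44 were lower when adjusted over the list alone. The ribosomal median was −5.46 (adjusted p = 1.63e-40; adjusted p = 0.253 with an estimated correlation). Of 7 mitochondrially encoded genes 6 were lower. The mitochondrially encoded median was −3.30 (adjusted p = 1.51e-09; adjusted p = 0.253 with an estimated correlation). Of 65 nuclear oxidative phosphorylation genes 38 were lower, 53 adjusted over the list alone, with COX7C of cytochrome c oxidase at −4.15 ± 0.54. The oxidative phosphorylation median was −1.83 (adjusted p = 1.15e-29; adjusted p = 0.253 with an estimated correlation). Of 38 cytoskeleton genes 17 were lower, 23 adjusted over the list alone, with ACTB at −4.73 ± 0.85 and TMSB4X at −6.42. The cytoskeleton median was −1.68 (adjusted p = 7.18e-15; adjusted p = 0.253 with an estimated correlation). Of 32 translation factor genes 13 were lower, 17 adjusted over the list alone. The translation factor median was −1.12 (adjusted p = 2.62e-08; adjusted p = 0.253 with an estimated correlation). Within a scan day one side is a single array (HD 4 on day 1, LD 3 on day 2), and the medians of these lists were −3.48 on day 1 and −5.05 on day 2 for ribosomal genes, −3.01 and −3.11 for mitochondrially encoded genes, −1.88 and −0.89 for oxidative phosphorylation, −1.61 and −0.59 for the cytoskeleton and −0.83 and −0.39 for translation factors.

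By the median, smaller shifts were found in the proteasome (5 of 42 lower, 10 adjusted over the list alone, median −0.57, camera adjusted p = 8.33e-07, or 0.471 with an estimated correlation). The same held for the spliceosome (10 of 55, 13 adjusted over the list alone, median −0.30, camera adjusted p = 6.83e-05, or 0.501) and mitochondrial ribosomal genes (10 of 73, 12 adjusted over the list alone, median −0.27, camera adjusted p = 4.89e-05, or 0.568). It also held for glycolysis (7 of 20, also 7 adjusted over the list alone, median −0.24, camera adjusted p = 0.000503, or 0.253), though the mean of this list was −1.62. Scaling to the 75th percentile turned these medians to 0.36, 0.63, 0.66 and 0.68. Zinc finger genes (ZNF441 and ZNF331 higher, ZNF428 lower, median 0.29, adjusted p = 0.00122; adjusted p = 0.654 with an estimated correlation) and olfactory receptor genes (none of 36 called, median 0.49, adjusted p = 0.00491; adjusted p = 0.654 with an estimated correlation) were placed above other genes. The zinc finger median is the difference between the mean floors (4.06 in HD, 3.77 in LD), and with one common floor the olfactory median was 0.25, so the first position is set by the floors and the second in part. Secretory (6 of 48 lower, adjusted p = 0.331), histone (2 of 18, 0.11), cell cycle (3 of 55, 0.625), mast cell (2 of 27, 0.195), heat shock (2 of 34, 0.203), immediate early (1 of 31, 0.547), cytokine (1 of 21, 0.768), cholesterol (1 of 28, 0.779) and vesicle genes (1 of 52, 0.696) did not pass as lists. The lower genes of the short counts were CKS1B, CKS2 and AURKB of the cell cycle, TAL1 and ALOX5AP of mast cells, HSP90AB1 and CCT8, DUSP6, CHMP2A, and the histone genes H1-2 and H3C7. Of these CKS2, TAL1, ALOX5AP, HSP90AB1, CCT8, DUSP6 and CHMP2A, and ZNF428, lost their calls without LD 1 (adjusted p from 0.0826 to 0.285), all but ALOX5AP without LD 2 (0.0503 to 0.213), and all with one common floor (0.0552 to 0.193). TAL1, CHMP2A and CCT8 also lost them without HD 1, HD 2 or HD 3 (0.0539 to 0.114), ZNF428 without HD 3 (0.0501), and CHMP2A and CCT8 without any Cell array (0.0626 to 0.0796). MIF, a cytokine, stood at −5.18 ± 0.83 and FDPS, of sterol synthesis, at −3.65 ± 0.56; adjusted over the list alone there were 7 secretory, 1 heat shock, no vesicle and no zinc finger genes lower, and the other lists in this group kept their numbers. CD63 changed by −2.43 ± 0.82 (adjusted p = 0.12), and with culture number as a block by −3.32 (adjusted p = 0.000243). No list of other cell types passed (adjusted p from 0.353 to 0.856); in them KRT19 was lower, and KRT18 was higher (1.69 ± 0.43), a call lost with one common floor and without HD 2, LD 2, LD 3 or any Cell array (adjusted p from 0.0504 to 0.112).

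The median of all tested probes was 0.28 in HD against LD and 1.20 after scaling to the 75th percentile, which gave 3 higher and 195 lower probes; normexp gave 336 and 1015, quantile normalization 237 and 755, and the series matrix values 289 and 1020. Called probes numbered 857 with culture number as a block, 756 with scan day as a block, 849 within scan day 1 (HD 4 alone for HD), 800 within scan day 2 (LD 3 alone for LD) and 1301 without LD 3.

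**Figure D4:**
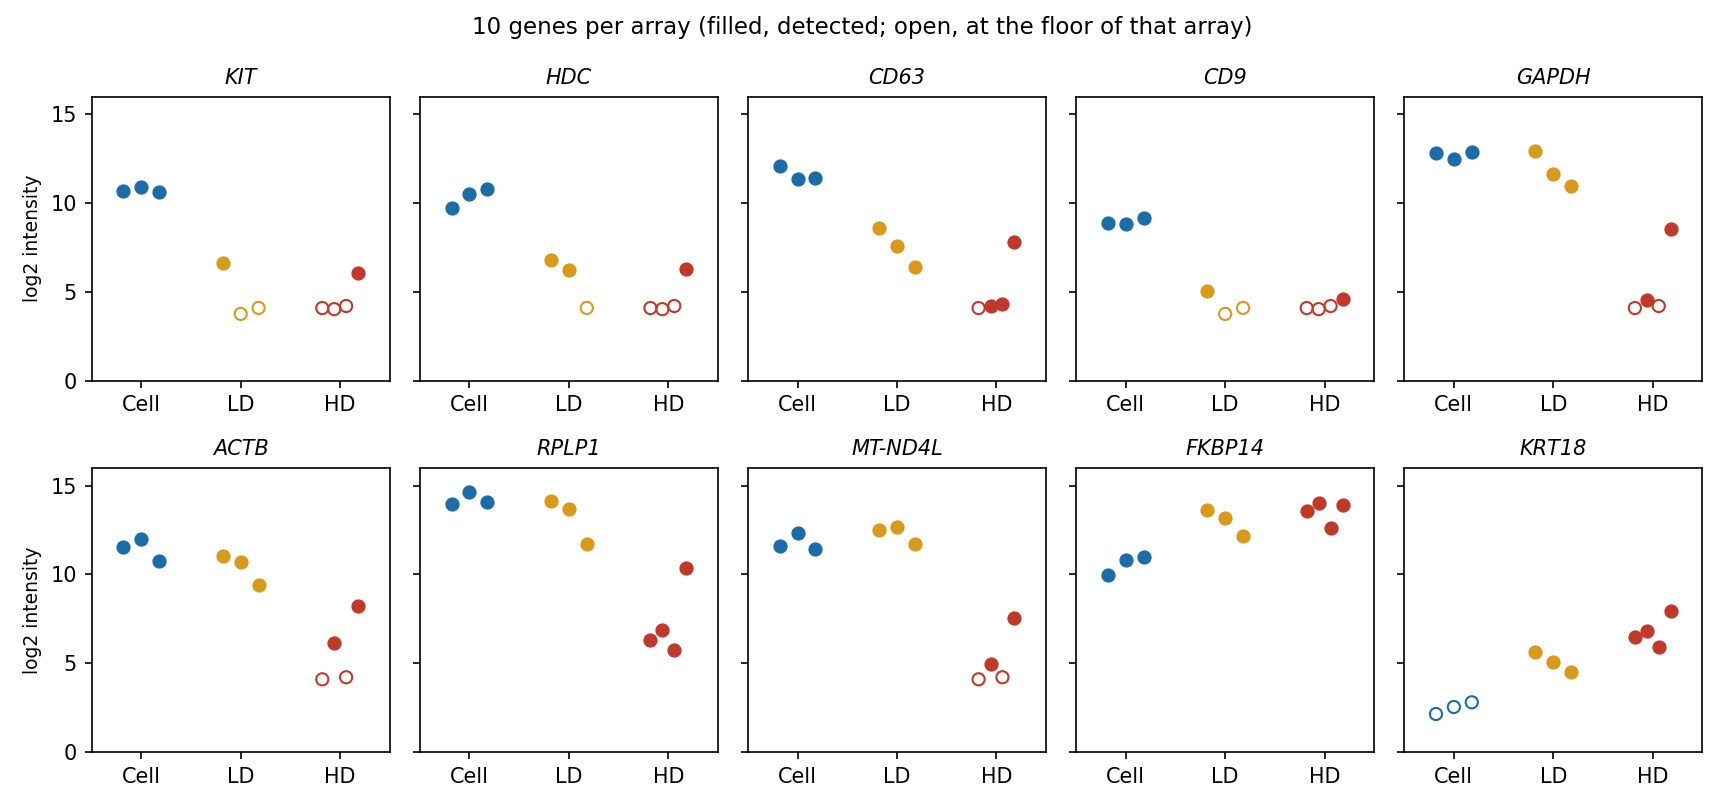
Log2 intensity of 10 genes on each array, grouped by Cell, LD and HD; filled points are detected and open points lie at the floor of their array. MT-ND4L averages 12.29 in LD and 5.19 in HD, while KIT is detected on 1 LD array and 1 HD array, and FKBP14 averages 13.53 in HD, 12.98 in LD and 10.60 in Cell, a call lost in both comparisons with a trended and robust variance.

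Most probes called in one fraction were called in the other, in the same direction. Of the probes called against Cell, 4404 were lower in both fractions and 400 higher in both, against 2521 and 47.9 if the lists were independent, and 1 probe moved apart, for GNG3, a G protein gamma subunit (−4.26 ± 0.44 in HD, 1.72 ± 0.47 in LD). MYOM3 (3.62 ± 0.49 in HD, 2.61 ± 0.52 in LD) and SLC11A1, a metal transporter of phagosomes (2.92 ± 0.57 and 2.38 ± 0.61), were among those higher in both, of which 38 were detected on every array of both fractions. With one common floor 17 were higher in both and 4197 lower, and SLC11A1 lost its call in LD; the 400 became 866 without Cell 3 and 237 without LD 2. The log2 fold changes of the comparisons correlated across probes at 0.815. Both use the same 3 Cell arrays, and simulated data with no true difference and with floors gave 0.672. The simulated covariance was 0.107 against the 1.72 observed, with 0.1 higher and 0.05 lower probes in common on average. The simulated fractions kept the Cell level of each probe. In the data 2660 lower calls had no detection in HD and 1510 none in LD. The simulation therefore does not show how many calls in common weak signal in both fractions would give.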

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

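The tests of the signal before scaling and of scan day, the allowance for blank spots and the comparison over 266 probes were chosen only after the result was seen. In 46 values of HD arrays tested for 1 array far from the others, 4 passed Dixon's limit (chance gives about 1 in 20), each with HD 4 as the array apart. The ratio of gap to range was 0.91 for the correlation with cells (0.141, 0.119, 0.106 and 0.489), 0.857 for the median ribosomal level (4.09, 4.62, 4.20 and 7.79), 0.833 for RPL7 (4.45, 5.11, 4.89 and 8.38) and 0.844 for RPS25 (5.53, 5.78, 5.21 and 8.86). Of the 56 named probes detected on 1 HD array, all 56 were detected on HD 4.

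HD 4 stands apart from HD 1 to HD 3. RNA of the LD kind or of the cells may be present in it. Across 6606 probes it correlated at 0.758 with the mean LD array and 0.583 with the mean Cell array. Over the 1687 of these probes detected on HD 4 the values were 0.764 and 0.653. With each profile cut at the level of its own 1687th brightest probe, over all 6606 probes, they were 0.766 and 0.784. The order depended on the treatment, so these sources cannot be told apart. Scan day cannot be told apart either, since HD 4 alone among HD arrays was scanned on day 1 and the LD gap in correlation between days was 0.125, against 0.366 in HD, with 1 LD array on day 2. A difference of the HD 4 culture, which has no partner, stays open and untested.

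The 127 probes higher in HD than in Cell and detected on every HD array may be raised by the scaling or may have more molecules in HD. Before scaling, their median log2 ratio of background-subtracted signal, HD over Cell, was 0.51, with −0.21, 0.83, −0.75 and 2.33 for HD 1 to HD 4 (SD 1.35), and 90 of 127 probes lay above Cell. The spread between arrays covers both explanations, and the RNA input is not stated, so they cannot be told apart.

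The low probes of both fractions could come from less labelled RNA of the same make-up as the cells. The share of an array's clearest probes found among as many of the brightest Cell probes was 42.5% at most in HD (7.25 to 42.5%, SD 16.2), against a bound of 75.3% set from Cell arrays at the same size (at least 85.3%). That bound makes no allowance for background: blank spots alone would give 274 probes on HD 1 and 146 on HD 3, where 202 and 207 were the clearest. Without the probes expected from blanks the share was still at most 16.7% on HD 2 and 50.5% on HD 4. Over the 266 probes detected on all 10 arrays, where no floors enter, HD arrays correlated with each other at 0.806 to 0.944 and with Cell arrays at 0.0821 to 0.541 (SD 0.174). LD 3, with fewer detected probes than HD 2 or HD 4, correlated with Cell arrays there at 0.833 or more. These probes had to be detected on HD 1 and HD 3, with 878 and 1825 detected probes against 1880 and 1698 expected from blanks. The choice favours probes that are bright in HD. Before scaling HD 1 to HD 4 lay above Cell at 25, 65, 6 and 139 of the 266 probes, and LD 1 to LD 3 at 34, 32 and 0. The shares argue against less RNA of the same make-up as the whole cause on HD 2 and HD 4. The correlations cannot decide, because their probes were chosen by detection on the HD arrays. On HD 1 and HD 3 the share cannot decide, because blanks alone would give so many of the clearest probes. Positive Control 1 spots, whose target is not stated, lay 7.89, 15.5 and 3.67 above background on HD 1 to HD 3. They lay 635 above it on HD 4 and 578 on LD 3, so LD 3 is no match in signal for HD 1 to HD 3. Less RNA as a part of the cause stays open on HD 4, which detected 493 of the 500 brightest Cell probes. Signal bound without a matching RNA was not tested, which limits the reading of HD 2, with its low control signal. In LD the share was 73.4% at most (67.6 to 73.4%, SD 3.03), and 69.5 to 79.3% with the same allowance, on both sides of the bound. Over the 266 probes LD arrays correlated with each other at 0.957 to 0.984 and with Cell arrays at 0.833 to 0.920 (SD 0.0307). These correlations, over the same chosen probes, go against less RNA alone, but the shares on LD 1 and LD 3 lie above the bound and go with it. Less RNA and a different make-up therefore cannot be told apart in LD. A biological difference between the fractions remains open as a hypothesis.

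Each comparison was refitted with the arrays of both groups split in other ways, and the real split is counted among the splits. For genes in HD against Cell 1 of 35 splits gave as many as the real 6023. The tested probes were chosen once with the real groups, 9281 of the 9333 being detected on every Cell array. This choice favours the real split, so the splits cannot exclude chance for this count. The highest other, 1356, sets Cell 1 to Cell 3 with HD 4 against HD 1 to HD 3, which is the split by scan day. With scan day as a block the real count is 5370. For genes in HD against LD 1 of 35 gave as many as 761, a share under 0.05 with these probes and all arrays taken as exchangeable. The highest other, 531, sets HD 4 with the LD arrays. For gene lists chance is not excluded: 4 of 35 splits gave as many as the 17 in HD against Cell (highest other 17, also the scan day split; 17 with scan day as a block) and 16 of 35 as many as the 11 in HD against LD (highest other 15). In LD against Cell the 10 splits are too few, for genes (1 of 10, real 5188, highest other 0) as for lists (4 of 10, real 14, highest other 15). These counts take all arrays as exchangeable. Splits that part all 3 culture pairs, as the real one does, number 8 in HD against Cell, 4 in LD against Cell and 8 in HD against LD with the real one, too few for a share under 0.05. The others among them reached 1356 genes and 17 lists in HD against Cell, 0 and 10 in LD against Cell and 531 and 12 in HD against LD. For the overlap of 4804 probes only the real one of 100 splits of all arrays gave as many. These splits keep the same probes and ignore the shared cultures, so they cannot exclude chance. The highest other, 4723, keeps the Cell arrays together and mixes HD with LD, so this test speaks to the difference from Cell and not to the parting of HD from LD.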

How the results depend on the processing

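One common floor, leaving out HD 1 with HD 3 or HD 4 with LD 3, detection at 5 SD and the brightest unflagged probe per gene were chosen after seeing the data. Of 197 results for named genes over all alternatives, 5182 values kept direction and side of the threshold, 374 lost a call, 38 gained one and 4 turned. Signal over background limits what can be measured: HD 1 detected 878 probes against 1880 expected at its blank rate and HD 3 1825 against 1698, and lowered probes end at the floors. At 5 SD Cell arrays detected 7248 to 8092, LD 713 to 2701 and HD 202 to 1448 probes. Where a cause is not given below, the cause was not tested.

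Counts of genes are given in the order HD against Cell (6023), LD against Cell (5188) and HD against LD (761), and in brackets where the brighter group was detected on every array (5046, 4848, 759). Normexp moved them to 3807, 994 (992) and 1351; scaling to the median of probes on all 10 arrays to 3262 (2818) and 2362 (2347); the 75th percentile to 2733 (697), 2 (2) and 198 (198); quantile normalization to 3394 in LD against Cell; the series matrix to 4004, 1106 (1104) and 1309. Fewer or more probes tested gave 120 (120), 22 (22) and 50 (50) with probes on all 10 arrays, and 21272 and 20063 without a filter, where floors enter as differences. Undetected values left missing gave 2151 (1831), 2617 (2550) and 352 (331), with fewer values per probe. Array weights, whose estimate stopped before converging, gave 8122 (1352) in HD against LD. Without LD 3 it was 1301 (1297), and without HD 4 and LD 3 1363 (1359). The overlap of 4804 became 2039 with the median of probes on all 10 arrays and 22 with probes on all 10 arrays only. A common floor gave 5156, 4245 and 517 genes, 16, 12 and 11 lists and an overlap of 4214.

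Lists called (17, 14 and 11) became 8 in HD against Cell and 6 in LD against Cell under quantile normalization, 1, 1 and 1 with probes on all 10 arrays, 0, 1 and 0 with an estimated correlation, and 18 in HD against LD without a filter. With the brightest unflagged probe they were 18, 14 and 11, the vesicle list passing in HD against Cell. A detection limit from all blank spots moved the difference in detected probes to −4612.25 in HD against Cell (exact p = 0.114), −2499.33 in LD against Cell (exact p = 0.4) and −2112.92 in HD against LD (exact p = 0.114); bright blanks raise that limit, which left 363 probes on Cell 3. Detected probes in HD minus LD turned to 177.5 within scan day 1 (exact p = 1, fewer arrays). CPA3 turned to −0.35 in HD against Cell and −0.35 in LD against Cell under quantile normalization, CD81 to 0.42 in HD against Cell at the 75th percentile, and CD9 to 0.37 in HD against LD with array weights.

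Leaving out each array in turn gave 5538 to 6580 (4797 to 5123), 4566 to 5573 (4401 to 4912) and 526 to 1301 (526 to 1297) genes, 17 to 19, 13 to 17 and 10 to 12 lists, an overlap of 4376 to 5178, differences in detected probes of −9434.67 to −7945, −7778.67 to −6258.17 and −2383 to −817.5, and a difference in correlation with cells of −0.619 to −0.486. The other alternatives, among them blocks by culture and scan day and a 2-fold minimum, left each total of genes, lists and shared probes within 1.5 times its main value.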

Other observations

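The levels where most genes were measured were chosen only after the result was seen.

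SNHG12, the host RNA of small nucleolar RNAs and the 1 tested member of the nuclear noncoding list, was lower than in Cell in HD (−1.84 ± 0.23 SE, detected on 1 of 4 arrays) and in LD (−1.63 ± 0.25, detected on 2 of 3). Of 1659 probes detected on every LD array 228 were detected on no HD array. Of 408 detected on every HD array 7 were detected on no LD array. These counts depend on array depth: HD 1 and HD 3 detected 878 and 1825 probes, against 1880 and 1698 expected from blanks. UBE2Q1, an enzyme of ubiquitin transfer, was at least 12.2-fold lower in HD than in LD, and CKS1B, a cell cycle kinase subunit, at least 5.61-fold lower. Against the cells, 9 probes were detected on every HD array and no Cell array and 7 on every LD array and no Cell array, against 4940 and 3531 the other way.

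One hypothesis was that messenger RNAs of membrane and secreted proteins, which are translated at the endoplasmic reticulum, are lower in extracellular RNA than other messenger RNAs of the same level in the cells. Genes of membrane or secreted proteins (1634) were compared with genes of cytosolic or nuclear proteins (2465) within 20 levels of Cell signal. The matched difference of the median log2 fold change was −0.0615 in LD (permutation p = 1e-04, the smallest that 10000 permutations can give; −0.11, −0.07 and −0.02 for LD 1 to LD 3) and 0.026 in HD (permutation p = 0.0044). The permutations exchanged classes between genes of the same level, so they take genes as independent and do not measure the spread between arrays. Both differences, −0.0615 and 0.026, lay on the side that the rule set beforehand counts against the hypothesis. The floors may set these differences, because 65.4 and 62.3% of the genes of both classes were mostly undetected in LD and 88.6 and 92.2% in HD. The hypothesis can therefore be neither kept nor dropped from them. At the 6 levels where most genes were measured the LD difference was −0.30 (398 against 832 genes, permutation p = 1e-04; −0.45, −0.33 and −0.10 per array; −0.27 without ribosomal genes), and HD had no such level. The test was first run with other classes (1509 against 2660 genes) and gave −0.0581 in LD and 0.0223 in HD. The classes were changed after that run. Transcript length was not tested, and the array files give none.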
